A study of Mus musculus with 6 samples.

How the data were processed

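Count matrices deposited by the authors for 6 libraries of mouse crypt cells were used, each with 32285 genes and 9245, 4304 and 5706 barcodes for the libraries labelled distal, middle and proximal colon and 5623, 4979 and 5316 for distal, middle and proximal small intestine. The values are counts of unique molecular identifiers (UMIs) and, per the submitters' processing notes, came from Cell Ranger 7.1.0 against mm10. Reads were not analysed here. Gene coordinates are those of GENCODE vM21 (GRCm38), in which 32158 of the genes were found by identifier. The cell filters, classes, gene lists, tests, rules of size and alternatives described below were written down before the data were examined, except where said otherwise. Nothing in the labels says whether the 6 libraries came from separate animals, and each region has 1 library.

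Cells were kept with at least 500 genes, at least 1000 UMIs and at most 25% mitochondrial counts. Doublets were scored with Scrublet per library, and the highest scores were removed at 0.8% per 1000 cells, which marked 6.41%, 3.01% and 4.29% of the colon and 4.30%, 3.83% and 4.09% of the small intestine cells. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were taken, and cells were clustered per organ with 15 neighbours by the Leiden method at resolution 1 and seed 0, giving 31 colon and 26 small intestine clusters. The title genes, Hox genes and genes of the label check were kept out of the variable genes. Clusters were named with 15 marker lists by the highest mean standardised expression, which had to reach 0.5, to lead the next class by 0.5 (stem-like and cycling were not set against each other) and to rest on at least 3 markers detected in a share of 0.1 of the cells. A cluster stayed unnamed if it mixed cycling and secretory markers, if its 10 leading genes held more markers of another class, or if its cells were shallow and none of its own markers was among those genes. The last reason left clusters 24 (165 cells, nearest to T or innate lymphoid) and 29 of the colon unnamed. Stem-like colon clusters 3 and 4 (857 and 853 cells) were named by score with 0 of their markers among the 10 leading genes. The marker lists were fixed in advance, and these thresholds for naming were set once the matrices could be read. The size of the stem-like class therefore rests on such markers. Epithelial values pool all clusters not named as immune or stromal, unnamed ones included, whose mean log Epcam was at least 1.

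For colon against small intestine, UMIs were summed per library and class with at least 20 cells in each library, for stem-like, cycling, absorptive and goblet-like cells. The sums were tested with edgeR's quasi-likelihood F test after its expression filter and scaling by trimmed means (TMM), with adjustment by Benjamini and Hochberg and a threshold of 0.05. Scaling, test and filter were also exchanged for others. Fold changes are log2 values with standard errors. Where a gene had 0 counts in an organ, the fold is a lower bound against 3 counts per library, and where it had 1 to 3 counts it is the ratio of counts with an exact counting interval. Of 23 gene lists fixed in advance 16 were tested as groups in stem-like cells by camera with a preset correlation of 0.01, and beside it with an estimated correlation and by fry. Counts of changed list members were also taken adjusted over the list alone. Shares of classes were compared by exact permutation over the 10 splits of the libraries. Of the list genes 3 (Mx1, Pla2g2a and Prac1) were absent by symbol.

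Regions had no replicate, so no test was made between them. CPM is the count of a gene over all UMIs of the class in a library, on the usual CPM scale, with exact Poisson intervals at 95%, and shares of cells have exact binomial (Clopper-Pearson) intervals. A gene marked a region when its CPM was at least 4-fold above that of the next library (taken at no less than 3 counts), with at least 50 UMIs and 50 CPM. For shares of cells with a UMI of Nox1 or Npy1r, cells were thinned to 3000 UMIs, and those with fewer were left out. Labels were checked in each colon and small intestine library with lists of regional genes, counting for each gene with at least 10 UMIs the library in which it was highest. In all 6 libraries the sex-linked genes gave a male pattern.

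Genes named in the text follow a rule fixed in advance. In stem-like cells these are the 10 largest rises and 10 largest falls among genes that passed, did not overlap between organs and averaged at least 50 CPM in the higher organ, and in other classes the first 5 of each. For each region and class they are the 7 genes with the largest fold that passed the rule of size. For each list they are the 2 to 4 tested members of highest mean CPM and members that passed. Title genes are always named. A few genes that the rule would name are not reported here. Mitochondrial, ribosomal protein, immunoglobulin, T cell receptor, haemoglobin and sex-linked genes and unnamed gene models were left out.

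Alternatives for the organ tests were size factors by relative log expression (RLE), library size alone, the DESeq2 Wald test, no expression filter, a block for position along the organ, at most 10% mitochondrial counts, doublets kept, resolution 2, clustering of all 6 libraries together, cells with at least 1 UMI of Lgr5 as stem-like cells, equal cell numbers thinned to 3000 UMIs, and each library left out in turn. Alternatives for shares were 1000 genes and 3000 UMIs per cell. Those for regions were 2-fold, 200 UMIs and 200 CPM, and TMM scaling, and those for the title genes no thinning and 1500 UMIs. Added after the label check were the block with the end colon libraries exchanged and the middle colon library alone against the small intestine.

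In a simulation from the stem-like sums with 14050 genes, edgeR recovered 17.5% of 97 genes changed 2-fold and 79.4% of 97 changed 4-fold, with 6 unchanged genes among 100 calls. In the same simulation camera separated a raised list (9.55e-22) from an unchanged list (0.866). Each gene was drawn independently there, so lists of correlated genes were not covered. The rule of size found 50 of 50 genes raised 8-fold and 0 unchanged genes in each of the 4 regional comparisons. Those counts were simulated with counting error only, from 1 profile shared by the 3 libraries of an organ. They do not cover differences between animals or in the clusters that make up a class. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.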

Results

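Crypts, the pits of the intestinal lining that hold its stem cells, were isolated from 3 regions of the mouse colon and 3 regions of the small intestine, and single cells were profiled by droplet RNA sequencing. Each of the 6 regions was represented by 1 library, so each organ had 3 libraries and no region had a replicate. The labels named the regions distal, middle and proximal. Total counts of unique molecular identifiers (UMIs) were 97987753, 83836177 and 109497379 in the libraries labelled distal, middle and proximal colon, and 137289068, 130121079 and 125138872 in those labelled distal, middle and proximal small intestine. After filtering, 6877, 3088 and 4221 colon cells remained in the same order, with median depths of 9402, 20092 and 18326 UMIs. In the small intestine 5005, 4427 and 4513 cells remained, with medians of 19734, 22580 and 21937 UMIs. Cells above the mitochondrial limit were 8.08%, 14.8% and 17.2% of those passing the gene and UMI minimums in the colon libraries, against 2.89%, 3.56% and 7.78% in the small intestine libraries.

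The first comparison was of the cell classes held by crypts of each organ. Goblet-like cells, which secrete mucus, made up 27.0% ± 8.51 (SD, n = 3) of colon cells and 5.41% ± 1.89 (SD, n = 3) of small intestine cells. Absorptive cells made up 11.3% ± 8.58 of colon and 38.4% ± 13.5 of small intestine cells, and cycling cells 6.42% ± 1.74 and 21.8% ± 3.71. Paneth-like cells, the antimicrobial cells of the small intestinal crypt base, made up 2.09% ± 1.61 of small intestine cells, and 0 such cells were named in the colon libraries. Stem-like cells made up 15.9% ± 8.76 of colon and 11.5% ± 1.98 of small intestine cells. B or plasma cells were 13.4% of the library labelled distal colon and 3.13% of the library labelled proximal colon. T or innate lymphoid cells were 13.9% of the library labelled distal colon and 0.356% of the middle colon library. With at least 1000 genes and 3000 UMIs per cell these immune shares were lower, with colon means of 0.775% for B or plasma cells (5.52% before) and 3.07% for T or innate lymphoid cells (6.41% before). Other shares moved as well. At most 10% mitochondrial counts gave 6.47% absorptive cells in colon and 19.9% stem-like cells in the small intestine, and goblet-like cells there were 10.3% with doublets kept. Clustering of all 6 libraries together gave 24.0% stem-like, 7.35% absorptive, 3.15% cycling and 2.63% T or innate lymphoid cells in colon. It also gave 18.0% stem-like, 9.34% goblet-like and 0.704% unnamed cells in the small intestine. A two-sided exact permutation test gave p = 0.1 for the goblet-like, absorptive, cycling, Paneth-like and myeloid shares (n = 3 per organ), the smallest p that 3 against 3 libraries allow, so no share can pass 0.05. The same exact test gave p = 0.4 for stem-like, B or plasma and T or innate lymphoid cells, 0.5 for tuft-like, 0.6 for enteroendocrine-like and 0.3 for unnamed cells (22.5% of colon and 15.8% of small intestine cells). Classes were named from markers, some of which themselves differed between the organs, so the shares carry that difference as well.

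**Figure D1:**
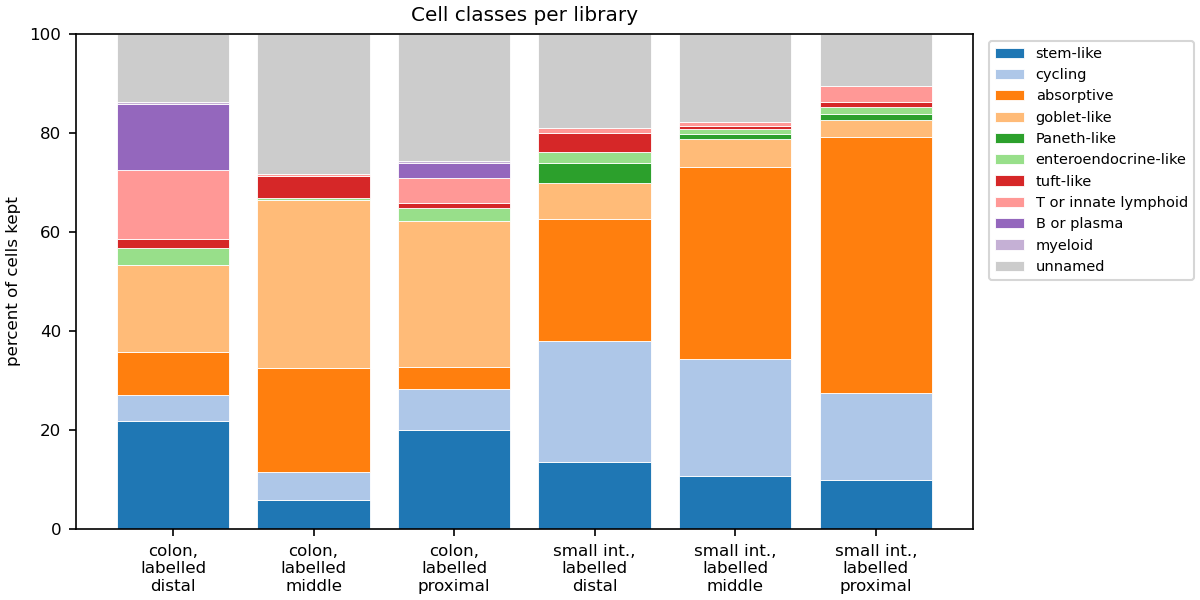
Percent of kept cells in each class, stacked to 100 for each of the 6 libraries, without error bars. Goblet-like cells took up 17.5% to 34.0% of the colon libraries, and absorptive cells 24.7% to 51.8% of the small intestine libraries.

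The regional labels were then set against genes whose position along the gut is known. Hoxb13, Hoxd10, Hoxd11, Hoxd12 and Hoxd13, posterior Hox genes that pattern the hindgut, were all highest in the library labelled proximal colon among epithelial cells. Hoxb13 (chromosome 11, 96194316 to 96197447 in GRCm38, the build called mm10) stood at 212 CPM (counts of a gene scaled to the UMIs of the class) there, against 56.3 CPM in the middle and 0.0390 CPM in the library labelled distal colon. Atp12a, a potassium pump subunit of the distal colon, stood at 21.3 CPM in the library labelled proximal colon and at 0.0130 CPM (1 UMI) in the one labelled distal colon. In all, 7 of the 9 distal colon markers with at least 10 UMIs were highest in the library labelled proximal colon, Hoxa13 was highest in the middle, and Scnn1b alone was highest in the library labelled distal colon (6.31 CPM against 4.67 CPM). In stem-like cells the anterior gene Hoxb6 stood at 116 CPM (95% exact Poisson interval 111 to 120.5) in the library labelled distal colon, 11.3 CPM in the middle and 0.150 CPM in the library labelled proximal colon. In the small intestine the same check placed 7 of 8 proximal markers, among them Gata4, Onecut2 and Fabp1, in the library labelled proximal, and 5 of 6 distal markers, among them Fabp6 and Slc10a2, in the one labelled distal. The letter codes in the names of the deposited matrices of the distal and proximal colon were also exchanged relative to the labels, 2 of 6 libraries. Colon libraries are therefore called by their labels throughout, and a direction along the colon is a direction between labels.

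**Figure D2:**
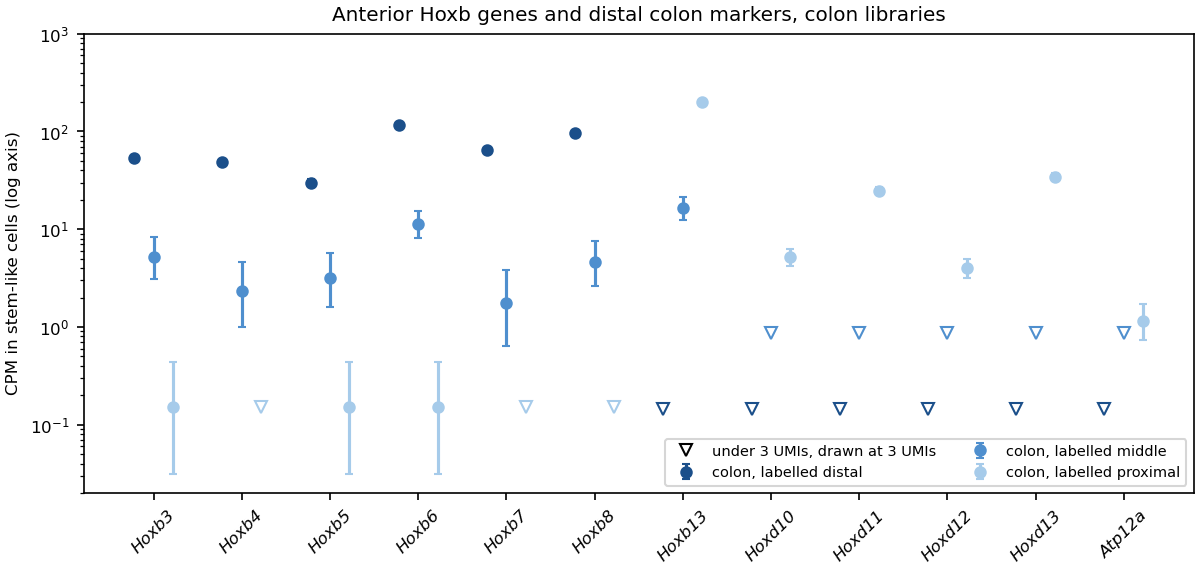
CPM in stem-like cells on a log axis for 6 anterior Hoxb genes and 6 distal colon markers in the 3 colon libraries, with 95% exact Poisson intervals for counting error only; open triangles mark values under 3 UMIs, drawn at the level of 3 UMIs. Hoxb6 stood at 116 CPM in the library labelled distal colon and 0.150 CPM in the one labelled proximal colon, and Hoxb13 at 0 and 201 CPM.

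The main comparison asked how stem-like cells of the colon differ from those of the small intestine. Olfm4 (chromosome 14, 79984081 to 80023139), a secreted glycoprotein that marks small intestinal stem cells, stood at 4223 ± 623 CPM (SD, n = 3) in the small intestine and at 0 UMIs in all 3 colon libraries, at least 10885-fold lower against a floor of 3 counts per library. Slco3a1, an organic anion transporter, stood at 273 ± 96.3 CPM in the small intestine and at 0.162 ± 0.111 CPM in the colon, a fall of 11.02 ± 0.44 on the log2 scale. Fam234b and AY761184, the latter annotated as a defensin-like gene, were at least 164.5-fold and 145-fold lower in colon. AY761184 was also among the 10 leading genes of the Paneth-like cluster. Whether free RNA of Paneth cells brought it into stem-like cells was not tested. The stomach and small intestinal gene Gkn3, which like Olfm4 also served to name the stem-like class, was 4358-fold lower by its counts (counting interval 782 to 172170), and Fabp1, a fatty acid binding protein, 2865-fold lower (514 to 113190). In the other direction Fut9, a fucosyltransferase, stood at 329 ± 363 CPM in colon and 0 in the small intestine, at least 1399.7-fold higher. Pcdh17, a protocadherin, rose by 10.12 ± 0.97 (log2 with standard error, SE), Foxd2os, a long noncoding RNA beside Foxd2, by 9.74 ± 0.52, and Ror1, a Wnt5a receptor, by 8.68 ± 1.08.

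St6galnac6, a sialyltransferase, rose in colon stem-like cells by 10.10 ± 1.86, and B3galt5, a galactosyltransferase, was 1212-fold higher by counts (335 to 10016). Nxpe4 was 1124-fold (384 to 5455) and the adhesion receptor Adgrb3 533-fold (182 to 2586) higher by counts, and Npas3, a transcription factor, rose by 9.53 ± 1.47. Hoxa11os was at least 249.7-fold higher; it overlaps Hoxa11 on the other strand (chromosome 6, 52244393 to 52249799 against 52242106 to 52245810), and whether counting used the strand is not given in the sources used here. The alpha-defensins Defa24, Defa30, Defa22 and Defa21, products of Paneth cells, stood at 437, 156, 105 and 103 CPM in small intestine stem-like cells and at 0 in colon, so that they were at least 1126-fold, 401-fold, 270.5-fold and 264-fold lower. These genes are near-identical copies, so the split of counts among them is uncertain. Whether free RNA of Paneth cells brought them into stem-like cells is taken up below and stays open. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3553 of 13879 genes passed an adjusted p of 0.05, 1730 higher and 1823 lower in colon. The 2 organs did not overlap for 6450 genes (46.5%, where chance gives 10%). Leaving out the distal, middle or proximal small intestine library left 1914, 964 and 1532 genes. Each gene named in these paragraphs kept its direction with any library left out, and 12 of the 20 calls (among them Olfm4, Slco3a1, Foxd2os, Pcdh17 and Ror1) held each time, while 8 ended without the middle small intestine library (Hoxa11os 0.0640, Nxpe4 0.0954, Defa21 0.102).

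**Figure D3:**
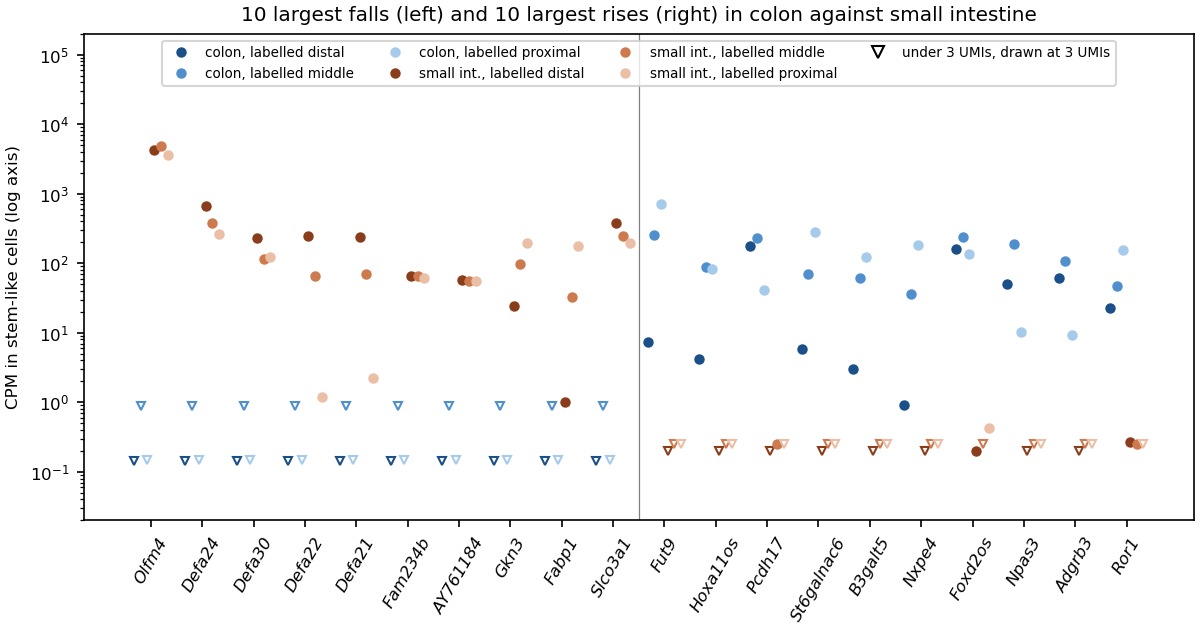
CPM in stem-like cells on a log axis for the 10 genes with the largest fall and the 10 with the largest rise in colon, 1 point per library and no error bars; open triangles mark values under 3 UMIs, drawn at the level of 3 UMIs. Olfm4 lay between 3583 and 4828 CPM in the small intestine libraries, and Fut9 between 7.33 and 722 CPM in the colon libraries.

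Of 23 crypt stem cell and Wnt target genes 11 fell in colon stem-like cells and 1 rose (12 fell adjusted over the list alone). The list's camera adjusted p was 3.09e-11 (adjusted p = 0.128 with an estimated correlation). Lgr5, the receptor that marks these stem cells, fell by 1.43 ± 0.28 on the log2 scale, from 697 ± 182 CPM in the small intestine to 249 ± 75.7 CPM in the colon. Smoc2 (-1.89 ± 0.16), Axin2 (-1.53 ± 0.19), Rnf43 (-0.94 ± 0.14), Sp5 (-5.10 ± 0.84) and Msi1 (-4.81 ± 0.82) also fell, as did Myc, Ascl2 and Prom1. Sox9, a transcription factor of the crypt base, rose by 0.45 ± 0.10. Slc12a2 (984 and 1789 CPM in colon and small intestine) and Lrig1 (309 and 339.6 CPM) did not pass. Of the list's members 8 also served to name the stem-like class, 7 of them among the falls. Stem-like colon clusters 3 and 4 had 0 markers of the class among their 10 leading genes, and cluster 5 had 1. Stem-like clusters 4 and 5 of the small intestine had 4 and 3. Whether a less strictly named colon class contributed to the falls of Lgr5 and the other listed genes stays open. The calls of Olfm4, Gkn3, Smoc2, Axin2, Rnf43, Sp5, Msi1 and Myc held with each library left out, and that of Lgr5 ended without the middle small intestine library (adjusted p = 0.0536), as did that of Prom1 (0.0961). The call of Ascl2 ended with 3 of the 6 libraries left out in turn (highest edgeR adjusted p = 0.0690, without the proximal small intestine library). Cell cycle genes followed with 5 of 20 lower and none higher, the replication factors Mcm2 (-1.47 ± 0.15), Mcm3, Mcm5 and Mcm7 and the cyclin Ccnd2 (5 also adjusted over the list alone; camera adjusted p = 0.0311, adjusted p = 0.5 with an estimated correlation). The list's adjusted p was 0.0562 without the middle colon and 0.0567 without the proximal small intestine library, and of the 5 calls only that of Mcm2 held with each library left out (Ccnd2 0.141 without the middle small intestine library).

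Hox genes of the A cluster were higher in colon. Among 12 anterior and central Hox genes tested, Hoxa2, Hoxa3, Hoxa4, Hoxa5 and Hoxa7 rose and none fell (5 also adjusted over the list alone; camera adjusted p = 8.98e-05, adjusted p = 0.192 with an estimated correlation). Hoxa3 rose by 4.90 ± 0.56, to 56.1 ± 20.1 CPM, and Hoxa7 by 6.56 ± 0.85. Hoxb3 to Hoxb9 did not pass, with Hoxb6 at 42.4 ± 63.8 CPM in colon and 15.2 ± 24.2 CPM in the small intestine. Of the posterior Hox list only Hoxa10 and Hoxa11 were expressed in enough libraries to be tested, and both rose, Hoxa10 460-fold by counts (127 to 3801) and Hoxa11 at least 10.7-fold. Among 13 regional transcription factors 3 rose and 4 fell, the same adjusted over the list alone. Klf4, a factor of differentiating epithelium, rose by 1.75 ± 0.49 to 57.1 ± 41.2 CPM, and Sox9 rose as well. Gata4, a factor of the upper small intestine, fell by 9.19 ± 1.25, Gata5 by 6.66 ± 0.57 and Hnf4a by 0.90 ± 0.22, and Onecut2 was 2331-fold lower by counts (645 to 19255). Hnf4g (409.5 and 449 CPM) and Cdx1 (126 and 123 CPM) did not pass. The list's camera adjusted p was 0.12 (adjusted p = 0.266 with an estimated correlation), and its fry adjusted p 0.000236. Without the distal small intestine library camera gave 0.00579 (adjusted p = 0.149 with an estimated correlation). Without the middle small intestine library the calls of Klf4 (adjusted p = 0.148), Hnf4a (0.0937), Sox9 (0.104) and Onecut2 ended, while those of Gata4, Gata5, Hoxa2, Hoxa3, Hoxa5, Hoxa7 and Hoxa10 held with each library left out. The call of Hoxa4 ended without the proximal small intestine library (0.0572), and that of Hoxa11 without the middle one (0.0719).

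Of 16 lipid absorption genes 13 fell in colon stem-like cells and 1 rose, the same adjusted over the list alone. Apob, the core protein of chylomicrons, fell by 3.94 ± 0.17, Apoa1 by 6.19 ± 0.46, Dgat1 by 2.58 ± 0.24 and Mttp by 1.99 ± 0.33, and the cholesterol transporter Npc1l1 was 213-fold lower by counts (37.8 to 8464). Acsl5, Slc27a4, Plin2, Plin3, Mogat2, Apoc2, Apoc3 and Fabp1 also fell. Scarb1, a lipoprotein receptor, rose by 2.73 ± 0.58, and Fabp2 stood at 227 and 253 CPM without passing. The camera adjusted p was 8.32e-11 (adjusted p = 0.128 with an estimated correlation). Of 8 carbohydrate genes 4 fell and none rose, the same adjusted over the list alone (camera adjusted p = 3.05e-05, adjusted p = 0.124 with an estimated correlation). Sis, the sucrase of the brush border, was at least 38.1-fold lower, Khk fell by 2.14 ± 0.34 and the lactase gene Lct by 1.43 ± 0.31. Of 8 bile acid genes Abcc2, an export pump (-5.49 ± 0.29), and Nr0b2 fell and none rose, the same adjusted over the list alone (camera adjusted p = 0.0190, adjusted p = 0.256 with an estimated correlation); the list's adjusted p was 0.126 without the middle colon, 0.0691 without the library labelled proximal colon and 0.0654 without the distal small intestine library. In lymphoid cells of the small intestine the 13 lower lipid genes stood at 2.09, 0.191 and 0.795 times the UMIs per cell of stem-like cells in the distal, middle and proximal libraries. Acsl5, Plin2 and Plin3 among them had 1638, 1625 and 1159 UMIs even in colon stem-like cells. They are thus not limited to absorptive cells, and the sum in lymphoid cells need not be free RNA alone. Without the middle small intestine library 9 of the 14 lipid calls ended (Scarb1 0.0844), as did those of Lct (0.0900) and Nr0b2 (0.0744), those of Apoa1, Apob, Dgat1, Mttp and Npc1l1 not among them.

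Antimicrobial genes fell in 11 of 19 cases and rose in 1 (2 adjusted over the list alone), with a camera adjusted p of 3.41e-15 (adjusted p = 0.124 with an estimated correlation). Besides the alpha-defensins, Lyz1, the Paneth cell lysozyme, fell by 9.45 ± 0.87, Itln1, a lectin, by 5.72 ± 0.56 and the goblet cell lectin Zg16 by 1.76 ± 0.42. Defa17, Mptx2 and Defa26 were at least 75.0-fold, 15.6-fold and 14.1-fold lower, and Reg3a was 49.0-fold lower by counts (13.2 to 411). Reg4 rose by 3.19 ± 0.95, and Pigr (1579 and 1253 CPM) and Lypd8 (419 and 433 CPM) did not pass. Of the 11 genes that fell 9 were Paneth cell markers, which lymphoid cells of the small intestine also held at 0.260 to 0.567 times the UMIs per cell of stem-like cells. The calls of Zg16 and Reg4 ended without the middle small intestine library (adjusted p = 0.0875 and 0.160), as did those of Defa21 and Defa22 (0.102 and 0.114).

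Mucin and glycosylation genes rose in 5 of 13 cases and fell in none (6 adjusted over the list alone; camera adjusted p = 0.00106, adjusted p = 0.157 with an estimated correlation). Muc2, the gel-forming mucin of goblet cells, rose by 3.44 ± 0.74 to 161.5 ± 116.5 CPM, and C1galt1 rose by 0.54 ± 0.13. Goblet-like cells were the larger share in colon, and whether their free RNA contributed to the rise of Muc2 was not tested. Fut2, a fucosyltransferase, was 492-fold higher by counts (136 to 4065) and its call held with each library left out, while those of Muc2 (adjusted p = 0.0750), C1galt1 (0.118), St6galnac6 and B3galt5 ended without the middle small intestine library. Muc13 (297 and 407 CPM) did not pass. Of 15 ion and water transport genes 2 rose and 5 fell (3 rose adjusted over the list alone), with a median log2 of -0.09, a mean of 0.83 and a camera direction of down at adjusted p = 0.954, which turned up with library size as the only scaling. Car2, a carbonic anhydrase, rose by 7.79 ± 0.49 to 359.5 ± 60.5 CPM and Slc4a4 by 0.71 ± 0.16. Slc26a3, Kcnq1, Aqp1 and Slc26a6 fell, and Cftr (794 and 707 CPM) did not pass. The calls of Car2 and Slc26a3 held with each library left out, and without the middle small intestine library 5 of the 7 calls ended (Slc4a4 0.106).

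Of 8 NADPH oxidase genes, which make superoxide or carry its regulation, Nox1 and Rac1 rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.0741, and 0.0130 without the distal small intestine library, where adjusted p = 0.316 with an estimated correlation). Noxo1 and Noxa1, the partner subunits of Nox1, stood at 84.6 and 82.1 CPM and at 50.1 and 33.1 CPM without passing. Of 13 retinol and xenobiotic genes Adh1 (4.45 ± 1.16), Gstm1 (2.66 ± 0.40) and Gstm3 rose, and Rdh7 and Cyp3a25 were 127-fold (43.1 to 618.5) and 62.1-fold (16.8 to 519) lower by counts, the same genes adjusted over the list alone. This list had a median log2 of 0.28, a mean of -0.32 and a camera direction of up (adjusted p = 0.844). Of 13 dissociation and stress genes Hspa1a (5.04 ± 0.54) and Hspa1b (5.79 ± 0.62), a near-identical pair of heat shock genes, and Ier3 rose and Jund fell, the same adjusted over the list alone (camera adjusted p = 0.1304), and the list passed without the middle colon (0.000219, with 5 genes higher; adjusted p = 0.459 with an estimated correlation) or the proximal small intestine library (0.0383; adjusted p = 0.627 with an estimated correlation). Jun (370.4 and 362 CPM) and Fos (134 and 149 CPM) did not pass. Slc40a1, an iron exporter, rose as 1 of 6 iron genes (camera adjusted p = 0.811), with Fth1 at 1505 and 2168 CPM and Ftl1 at 676 and 736 CPM. Oas1a rose as 1 of 6 interferon-stimulated genes (median log2 -0.02, mean 0.00, camera direction up at adjusted p = 0.811), with Ifi27l2b at 99.0 and 132 CPM. Each of these 2 lists gave 1 gene adjusted over the list alone. Of 7 MHC class II genes, which present antigens, edgeR's test called 0 (also 0 adjusted over the list alone and at an unadjusted p of 0.05; camera adjusted p = 0.543), with Cd74 at 196 ± 262 CPM in colon and 85.2 ± 88.0 CPM in the small intestine. The calls of Nox1 (adjusted p = 0.0555), Rac1 (0.173), Adh1, Gstm3, Cyp3a25, Slc40a1, Oas1a, Ier3 and Jund ended without the middle small intestine library; those of Gstm1, Rdh7, Hspa1a and Hspa1b held with each library left out. In all, 8 of 16 lists passed camera's threshold with a preset correlation, and 0 with an estimated one, while fry called 9. Splits of the libraries that mixed the organs also called 4 to 8 lists with the preset correlation, though part of the organ difference stayed in those splits.

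In cycling cells Olfm4, the small intestinal stem cell marker, stood at 1179 ± 69.8 CPM in the small intestine and 0 in colon (at least 3310.2-fold lower), and Defa24 and Defa30 were at least 665-fold and 211-fold lower. Whether free RNA of Paneth cells brought these defensins into cycling cells was not tested. Slco3a1 was 3539-fold lower by counts (635 to 139790) and Onecut2, a factor of the upper small intestine, 1524-fold (422 to 12585). Mptx1, a pentraxin, rose by 14.78 ± 3.44, to 10058 CPM in the library labelled proximal colon against 0.727 CPM in the one labelled distal colon. Car1, a carbonic anhydrase, went the other way between these colon libraries (3.30 and 890.1 CPM) and rose by 12.34 ± 2.91 over the small intestine. St6galnac6 was at least 1138-fold higher, and Fut9 and Pcdh17 were 11219-fold (3105 to 92658) and 3261-fold (1115 to 15821) higher by counts. In edgeR's test 4854 of 14187 genes passed, 2382 higher and 2472 lower in colon, and 7482 genes (52.7%, chance 10%) did not overlap between organs. The distal, middle or proximal small intestine library left out gave 3080, 1912 and 2693 genes, and the calls of Mptx1 (adjusted p = 0.0815), Car1 (0.0837), Onecut2 and St6galnac6 (0.0505) ended without the middle one, that of Fut9 (0.0595) without the proximal one.

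In absorptive cells the apolipoprotein genes were among the leading falls; Apoa1, Apoa4, Fabp1 and Car1 also served to name the class. Apoa1 stood at 8669 ± 2138 CPM and Apoa4 at 3025 ± 3356 CPM in the small intestine, and both at 0 UMIs in colon, at least 13955-fold and 4869.9-fold lower. Fabp1 fell by 15.75 ± 2.03, and the lactase gene Lct and the glucose transporter Slc2a2 were at least 778-fold and 530.2-fold lower. Car1 rose by 16.73 ± 2.25, with 29004 CPM in the library labelled distal colon and 1011 CPM in the one labelled proximal colon. Cyp2d34 and Cyp2d12, related cytochrome P450 genes whose counts may be split between copies, were at least 2147-fold and 646-fold higher. Tgm3, a transglutaminase, and Sval1 were 9314-fold (3186 to 45178) and 8076-fold (2234 to 66708) higher by counts. Sval1 was also among the 10 leading genes of goblet-like colon cluster 2, and free RNA of goblet cells was not tested as its source. In edgeR's test 3801 of 12702 genes passed, 1904 higher and 1897 lower in colon, and 5955 genes (46.9%, chance 10%) did not overlap. Counts were 2343 without the middle colon and 1902 without the middle small intestine library, without which Cyp2d12 (adjusted p = 0.0826), Sval1 (0.103) and Tgm3 (0.0589) did not pass.

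In goblet-like cells the leading falls in colon were Paneth and enterocyte genes. The 9 Paneth markers lower in colon stem-like cells, summed, stood at 114, 56.1 and 78.1 UMIs per small intestine goblet-like cell (distal, middle and proximal). Lymphoid cells of the same libraries held 20.4, 6.93 and 3.32 UMIs per cell. An equal amount of free Paneth RNA in every cell would not give that gap, which argues against it as the main source of the sum. Whether free RNA brought in the enterocyte genes was not tested. Defa24 stood at 3642 ± 1048 CPM in the small intestine and at 2 UMIs in all colon libraries, and Defa17 and Defa30 were at least 1824-fold and 1364-fold lower in colon. Fabp1 was 22357-fold lower by counts (4010.2 to 883270), and Apoa4 at least 1171.5-fold. Plet1, a surface protein of epithelial progenitors, and Ccn3, a matricellular protein, stood at 338 ± 403 and 222 ± 135 CPM in colon and at 0 in the small intestine, at least 399.95-fold and 263-fold higher. The noncoding RNA Meg3, Nxpe2 and Cmah, which makes the sialic acid Neu5Gc, were at least 130.2-fold, 95.1-fold and 83.7-fold higher. In edgeR's test 4368 of 13177 genes passed, 2221 higher and 2147 lower (50.8% higher), and 7351 genes (55.8%, chance 10%) did not overlap. With doublets kept, 2746 of the calls were shared with these 4368, and 2535 of the shared ones kept their direction. Resolution 2 gave 2539 shared and 2339 in the same direction, and clustering of all 6 libraries together 2699 and 2541. Some goblet-like calls thus turned round in these settings. With library size as the only scaling 75.0% of the calls were higher in colon, a shift of 0.407 log2 in the median of all genes (0.133 in absorptive cells). Without the middle or proximal small intestine library 1997 and 2584 genes passed, and the calls of Plet1 (adjusted p = 0.117), Meg3 (0.0964), Cmah (0.0627) and Apoa4 ended in each case (Apoa4 0.0541 without the proximal library).

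Across the 4 classes, 782 of the 11732 genes tested in each changed in the same direction in all, 348 higher and 434 lower in colon. Nothing in the labels says that the libraries came from separate animals, and the spread in these tests is that between regions of an organ.

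The series title names Nox1 and Npy1r as marks of regional stem cells of the colon, so both were followed through the 6 libraries. Nox1 (chromosome X, 134086421 to 134221956, minus strand) encodes the superoxide-producing oxidase of the colon epithelium. In stem-like cells it stood at 29.8 CPM (95% exact Poisson interval 27.5 to 32.2) in the library labelled distal colon, 187 CPM (173 to 202) in the middle and 107 CPM (103 to 112) in the library labelled proximal colon. The small intestine libraries held 11.7, 9.82 and 7.21 CPM from distal to proximal, and Nox1 was higher in colon by 3.50 ± 0.61 (edgeR adjusted p = 0.01003), with adjusted p = 0.0555 without the middle small intestine library. Npy1r (chromosome 8, 66697192 to 66706792, plus strand), a receptor of neuropeptide Y and peptide YY, had 0 UMIs in stem-like cells of the library labelled distal colon, with an upper limit of 0.178 CPM. It stood at 13.6 CPM (10.0 to 18.1) in the middle and 34.0 CPM (31.5 to 36.6) in the library labelled proximal colon. All 3 small intestine libraries had 0 Npy1r UMIs in stem-like cells, with upper limits of 0.245, 0.309 and 0.313 CPM. Stem-like cells came mostly from clusters 3 and 5 in the library labelled distal colon, cluster 5 in the middle and cluster 4 in the library labelled proximal colon (99.8% of its stem-like cells), so cluster and library were hardly separable there.

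By cell, with each thinned to 3000 UMIs, Nox1 was detected in 7.06% of stem-like cells (exact binomial interval 5.80 to 8.48%) of the library labelled distal colon, 34.1% (27.2 to 41.5%) of the middle and 23.3% (20.4 to 26.3%) of the library labelled proximal colon. B or plasma cells, which should lack it, gave 7.89% (6 of 76) in the library labelled distal colon and 3.13% (1 of 32) in the one labelled proximal colon, at median depths of 1804 and 2231 UMIs before thinning against 13136 and 20981 in the stem-like cells. The background interval (2.95 to 16.4%) covers the 7.06% of the library labelled distal colon, and the shallow B or plasma cells there had Nox1 at 26.1 CPM. Absorptive and goblet-like cells of that library had 5.37 and 6.80 CPM. Its stem-like cells held 617 Nox1 UMIs in 1509 cells. Its B or plasma cells held 49 in 923 cells, and its T or innate lymphoid cells 31 in 954. A background equal in every cell would thus be the smaller part of the stem-like value, and its exact size stays open. Thinning left out 35, 3 and 14 stem-like cells; unthinned shares were 25.7%, 78.6% and 66.8%. Npy1r was detected in 0 of 1474, 1.68% and 9.28% (7.39 to 11.5%) of thinned stem-like cells in the same order, and in 0 B or plasma cells; unthinned shares were 0, 17.6% and 44.7%. In the library labelled proximal colon 275 stem-like cells held both transcripts unthinned, where independence gives 252, and 20 held both thinned, where it gives 17.9. Cycling cells followed the stem-like order for Npy1r, at 0, 10.8 and 39.4 CPM, and had Nox1 at 24.0, 71.6 and 78.6 CPM. Npy1r was not limited to these classes. In the library labelled proximal colon tuft-like cells had Npy1r at 84.1 CPM (63.3 to 109, 55 UMIs in 46 cells), above the stem-like value. Enteroendocrine-like, goblet-like and absorptive cells there had it at 24.95, 7.497 and 1.314 CPM. Enteroendocrine-like cells of the library labelled distal colon had it at 146.6 CPM. Absorptive cells had Nox1 at 5.37, 7.29 and 19.7 CPM in the colon libraries. Over all epithelial cells Nox1 was highest in the library labelled proximal colon, at 55.7 CPM against 39.1 CPM in the middle, and at most 10% mitochondrial counts gave shares of stem-like cells of 22.2% in the middle and 21.0% in the library labelled proximal colon. The middle library had 0 B or plasma cells to give a background. These intervals and limits cover counting error only, and with 1 library per region no test between regions was possible.

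**Figure D4:**
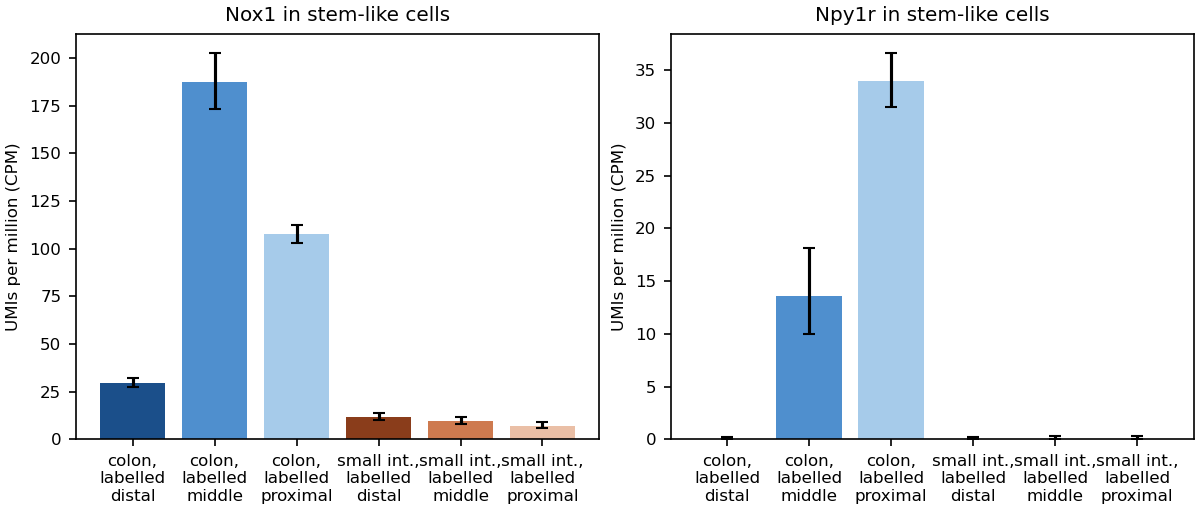
CPM in stem-like cells for Nox1 (left) and Npy1r (right), 1 bar per library, with 95% exact Poisson intervals for counting error only. Nox1 stood at 187 CPM in the middle colon library (182 cells), and Npy1r at 34.0 CPM in the library labelled proximal colon (844 cells).

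Regions of the colon were compared in stem-like cells by size alone, taking genes at least 4-fold above the next library. The library labelled distal colon was marked by Car1 at 160 CPM, against 1.74 CPM in the middle and 2.4985 CPM in the library labelled proximal colon, and by the anterior genes Hoxb7 (64.9 CPM), Hoxb8 (95.9 CPM), Hoxb3 (53.9 CPM) and Hoxb6. Isx, a repressor of vitamin A uptake, stood at 71.6 CPM there and at 0.2499 CPM in the library labelled proximal colon. Mgat4c, a glycosyltransferase, stood at 96.6 CPM against 12.5 CPM in the middle. The middle library was marked by Retnlb, an antibacterial peptide of goblet cells, at 99.1 CPM against 3.52 CPM in the library labelled distal colon, by the MHC class II genes Cd74 (497 CPM), H2-Ab1, H2-Aa and H2-Eb1, and by Gpc6 and Clca1. Its stem-like class held 182 cells. Retnlb and Clca1 were also among the 10 leading genes of goblet-like cluster 6, mostly of this library, and free RNA of goblet cells was not tested as their source. The library labelled proximal colon was marked by B3gnt7 (209.5 CPM against 4.64 CPM in the middle), the membrane mucin Muc3 (666 against 43.2 CPM), Nxpe2 (508 against 36.8 CPM), transferrin, Trf (83.9 against 4.35 CPM), Rdx, Sh3bgr and Hoxb13 (201 against 16.5 CPM). The rule of size took 51 genes, 13 of the library labelled distal colon, 7 of the middle and 31 of the library labelled proximal colon. The intervals of the named genes did not overlap those of the next library. Their choice by a lead of at least 4-fold with at least 50 UMIs made that likely beforehand, and no replicate checks the differences. With cells limited to 10% mitochondrial counts Mgat4c turned round, to -0.725 log2 against the next library.

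**Figure D5:**
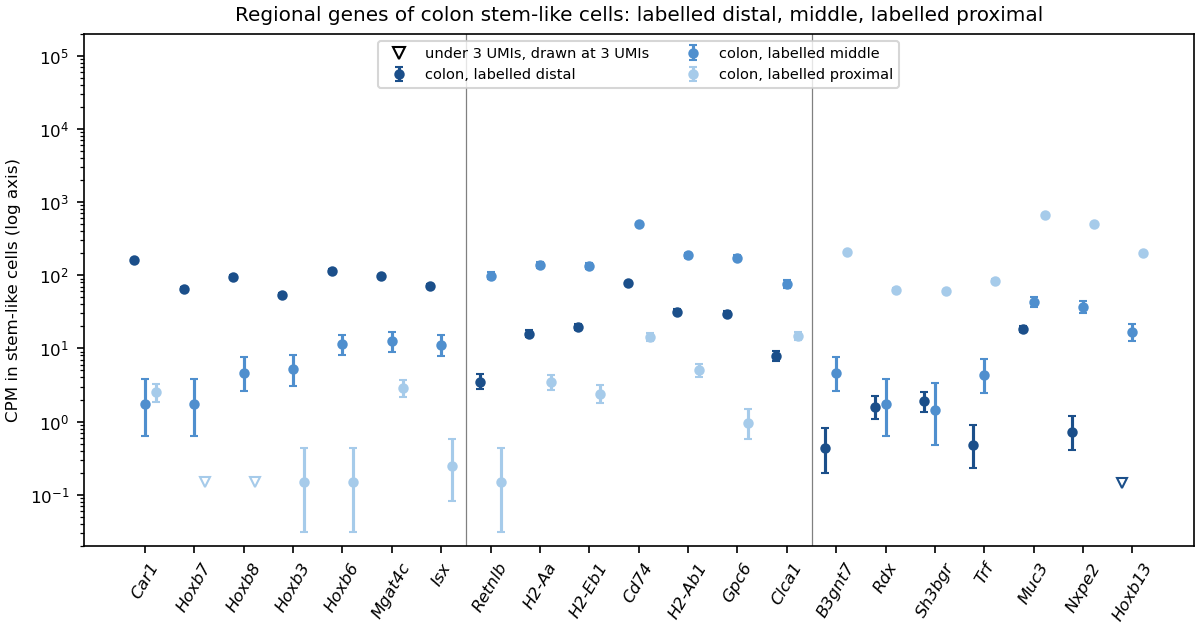
CPM in stem-like cells on a log axis for the 21 genes named by the rule of size, in 3 blocks by the library in which each was highest, with 95% exact Poisson intervals for counting error only; open triangles mark values under 3 UMIs, drawn at the level of 3 UMIs. Car1 stood at 160 CPM and Muc3 at 666 CPM in the library that each marked.

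In absorptive cells of the colon the library labelled distal colon was marked by the antibacterial lectins Reg3b (1441 CPM against 5.11 CPM in the middle) and Reg3g (244 against 2.18 CPM), close copies whose counts are less certain, by the bile acid transporter Slc10a2 (262 against 3.69 CPM), the esterase Ces1g (149 CPM), the defensin Defb37 (97.0 CPM), and by Osr2 and Hoxb6. The middle library was marked by Aqp4, a water channel (1028 CPM against 68.7 CPM in the library labelled distal colon), Ly6m (269.7 CPM), the interferon-inducible GTPase Iigp1 (86.4 against 5.07 CPM), and by the MHC class II genes Cd74 (545 CPM), H2-Aa (238 CPM), H2-Ab1 and H2-Eb1. The library labelled proximal colon was marked by Fxyd4, a regulator of the sodium pump (505 CPM against 0.922 CPM in the middle), Sval1 (1397 against 25.5 CPM), the trypsin inhibitor Spink1 (2681 against 54.1 CPM), Slc37a2 (514 CPM) and Mettl7a2. The goblet cell genes Zg16 (10307 against 224 CPM) and Tff3 (2272 against 92.5 CPM) also marked it. Sval1 was among the 10 leading genes of goblet-like cluster 2, and Spink1, Zg16 and Tff3 among those of goblet-like cluster 17, both mostly or wholly of this library. Whether free RNA of goblet cells or doublets brought these genes into its absorptive cells was not tested. The rule took 89 genes, 33, 8 and 48 from the libraries labelled distal, middle and proximal. The class rested on 187 cells in the library labelled proximal colon, all of cluster 20, against 590 and 646 cells, mostly of cluster 11 and of clusters 14 and 21; with a finer clustering the rule took 171 genes.

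In stem-like cells of the small intestine the distal library was marked by the transcription factors Klf12 (86.8 CPM against 1.007 CPM in the middle) and Tshz2 (79.2 against 4.78 CPM), by Bex1 (216 against 36.0 CPM), Adcy8, an adenylate cyclase (103 against 15.5 CPM), and Fstl4. Reg3b (251 CPM against 56.8 CPM in the proximal library) and Reg3g (197 against 45.3 CPM in the middle) also marked it. The proximal library was marked by the lipid and retinol binding proteins Fabp1 (179 against 32.8 CPM in the middle) and Rbp2 (82.0 against 18.3 CPM), Dmbt1, a mucosal scavenger protein (357 against 82.5 CPM), and Cyyr1 (51.8 against 12.2 CPM). The rule took 12 genes, 7 distal and 5 proximal, and 0 were highest in the middle library; no test was possible. Cluster 5 held 95.5% of the distal stem-like cells and cluster 4 held 70.2% of the middle and 98.4% of the proximal ones.

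In absorptive cells of the small intestine Fabp6, the ileal bile acid binding protein (chromosome 11, 43596049 to 43601540), stood at 27650 CPM in the distal library, 155 CPM in the middle and 0.0978 CPM in the proximal library. The bile acid transporter Slc10a2 stood at 354 CPM in the distal library against 5.49 CPM in the middle, and Saa1, an acute phase protein, at 197 against 5.32 CPM. Slc25a48, the sulfite oxidase Suox (115 CPM), Tmigd1 (671 CPM) and Mfhas1 were also distal. The proximal library was marked by Tmprss15, the enteropeptidase that activates trypsin (chromosome 16, 78953008 to 79091097), at 126 CPM against 0.124 CPM in the middle, and by the alkaline phosphatase Akp3 (59.4 against 0.174 CPM). S100g, a calcium binding protein, stood at 250.4 CPM in the proximal library against 5.99 CPM in the middle, and Reg1, a secreted lectin, at 3939 against 234 CPM. Sult6b2 (277 CPM), Cyp2c29 (51.2 CPM) and Bbox1 (58.0 CPM) completed the proximal genes. The rule took 43 genes, 21 distal and 22 proximal, and 0 highest in the middle. Intervals of the named genes, for counting error alone, did not overlap, which the rule of size made likely beforehand.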

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

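The tests of exchanged labels, of depth, of a general dissociation response, of 1 Paneth cell source and of the splits were chosen after the results had been seen. Those of heat shock genes in lymphoid cells and of free RNA were chosen before.

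Hoxb13, Hoxd10 to Hoxd13, Atp12a and Scnn1g, genes of the distal colon, were highest in the library labelled proximal colon, 7 of the 9 distal colon markers. The partner pattern was present as well, since 6 of 6 anterior genes from Hoxb3 to Hoxb8 were higher in the library labelled distal colon. Both may follow from exchanged labels, which the exchanged letter codes in the matrix names would also give; a true reversal of these Hox genes in the colon stays open, as no other record of the tissue was analysed here. Lower depth of the library labelled distal colon does not account for it, because the counting intervals of all 7 of 7 such markers were apart. Under an exchange, Npy1r of stem-like cells (34.0 CPM) would belong to the distal colon. Their Nox1 would then be lowest (29.8 CPM) in the proximal colon.

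Hspa1a and Hspa1b, chaperones of the heat shock response, rose in colon stem-like cells. In T or innate lymphoid cells they had 435 UMIs in colon against 0 in the small intestine, a ratio of 43.5 against a floor of 3 counts over the pooled small intestine cells (exact lower limit 35.2), so handling of the colon tissue, which reaches every cell of a library, may have raised them. A biological difference of the organ in both kinds of cell was not tested. Of the other 11 dissociation and stress genes 1 (Ier3) rose, which speaks against a general dissociation response, but that list passed camera without the middle colon library (adjusted p = 0.000219, 5 genes higher; adjusted p = 0.459 with an estimated correlation), so a weaker response stays open.

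Paneth cell genes such as Defa24 and Lyz1 stood in stem-like cells of the small intestine, and free RNA of Paneth cells may have carried them there. Lymphoid cells held 0.368 times the UMIs per cell of stem-like cells (median of 3 libraries, 0.260 to 0.567), a level that leaves this open. The mix of the Paneth genes matched that of Paneth-like cells, with 8 of 9 within 1.5-fold in each library at the fewest; Defa21 took 14.3% in stem-like and 15.2% in Paneth-like cells of the distal library and 0.456% and 0.673% in the proximal one. That would fit RNA from 1 Paneth cell source in stem-like cells better than their own expression of these genes. The mix was not the same in goblet-like cells. There Defa24 stood at 4415, 2449 and 4061 CPM and Defa30 at 237, 88.3 and 191 CPM (distal, middle, proximal). In Paneth-like cells Defa24 took 39.9%, 51.1% and 53.8% of these UMIs and Defa30 13.6%, 15.2% and 26.6%. RNA from 1 such source in every cell would thus not account for the goblet-like values of Defa24 and Defa30. For lipid absorption genes such as Apoa1 the ratio was 0.795 (0.191 to 2.09), which also leaves free RNA of absorptive cells open.

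Over the 10 splits of the 6 libraries into 3 and 3, 1 reached the real count in stem-like cells (3553 genes; highest other 0, with 397 at an unadjusted edgeR p of 0.05), 1 in cycling (4854; 0, with 557 unadjusted), 1 in absorptive (3801; 0, with 700 unadjusted) and 1 in goblet-like cells (4368; 0, with 467 unadjusted), in each case the real one. For gene lists 2 of 10 splits reached the real count of 8 (highest other 8). Splits that mixed the organs called 4 to 8 lists by camera with the preset correlation, though 0 genes passed in them. Each mixed split set unequal numbers of colon libraries against each other. Part of the organ difference thus stayed in it, and the rest widened its spread. The mixed splits are therefore not groups without an organ difference. They cannot tell whether passing camera at that setting marks a difference between the organs, and the 0 genes in them do not measure chance. With 10 splits no share under 0.05 is possible.

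Dmbt1, a mucosal scavenger protein, ran in opposite directions in stem-like cells of the organs between the libraries labelled distal and proximal, at 1896 and 58.2 CPM in colon and 80.3 and 357 CPM in the small intestine (difference of log2 ratios -7.18). Klf12 ran the other way, at 69.3 and 388 CPM in colon and 86.8 and 0.0849 CPM in the small intestine (10.90). In absorptive cells Saa1 stood at 175 and 6654.5 CPM in colon and 197 and 0.332 CPM in the small intestine (14.46), and S100g at 1739 and 285 CPM and at 5.59 and 250.4 CPM (-8.10). None of these was tested, as each region has 1 library, and they were picked for running in opposite directions. Under exchanged labels they would run alike, but the 2 of 5 stem-like and 12 of 28 absorptive genes at least 4-fold apart in both organs that run alike by label would then run in opposite directions. B or plasma cells were 13.4% and T or innate lymphoid cells 13.9% of the library labelled distal colon, and their genes were not analysed here. Npy1r stood at 146.6 CPM (128 to 167) in enteroendocrine-like cells of the library labelled distal colon. Hspa1a and Hspa1b together stood at 140.2 CPM in T or innate lymphoid cells of the colon.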

How the results depend on the processing

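Of 50 named organ genes 0 turned round over 873 values in other settings, 79 values lost the threshold and 25 genes kept it in all; 50 of the values are of the middle colon library alone, whose test takes its spread from the small intestine only. Of 78 list members 231 of 1447 values lost it and 27 kept it in all; of 16 lists 126 of 144 values stayed the same, and 0 lists passed with camera's estimated correlation. Of 68 regional genes 1 turned round over 298 values, Mgat4c in stem-like cells (-0.725 log2 at most 10% mitochondrial counts), and 21 never moved. At that limit the tuft-like and unnamed shares also turned round (-0.168 and -1.66 percent points). Leaving out 1 library gave 964 to 3895 genes in stem-like, 1912 to 5990 in cycling, 1902 to 4291 in absorptive and 1997 to 4559 in goblet-like cells, lowest without the middle small intestine and highest without the library labelled proximal colon. Stem-like counts were 5581 in cells with Lgr5 and 748 with equal cells thinned to 3000 UMIs. The position block gave 3184 in cycling and 2485 in absorptive cells, and 3947 and 3677 with the end colon libraries exchanged in the block. At 2-fold and at 200 UMIs and CPM, regional genes were 157 and 11 in colon stem-like, 451 and 37 in colon absorptive (171 at resolution 2), 33 and 3 in small intestine stem-like, and 196 and 21 in small intestine absorptive cells. Shares with Nox1 in the libraries labelled distal, middle and proximal colon were 25.7%, 78.6% and 66.8% unthinned and 3.86%, 23.8% and 13.8% at 1500 UMIs; at most 10% mitochondrial counts gave 9.02% (distal), 22.2% (middle) and 21.0% (proximal), doublets kept 23.7% (middle), and cells with Lgr5 18.9% (proximal). Npy1r was in 17.6% (middle) and 44.7% (proximal) unthinned, and in 3.81% (proximal) at 1500 UMIs. No paired analysis was possible because every library had replicate number 1, and the block above pairs the organs by labelled position only. Not run were regional absorptive colon genes with joint clustering and at 10% mitochondrial counts, which left 5 and 12 cells in the library labelled proximal colon.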

Other observations

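Some genes of absorptive cells ran alike between libraries of the same label in colon and small intestine, fewer than ran in opposite directions. Slc51a, a bile acid exporter, stood at 135 CPM in the library labelled distal colon and 0.438 CPM in the one labelled proximal colon, and at 1024.5 and 209 CPM in the distal and proximal small intestine. Prss23, a serine protease, stood at 82.2 and 11.8 CPM in colon and 81.7 and 0.919 CPM in the small intestine, and Adh1, an alcohol dehydrogenase, at 34.8 and 313 CPM and at 17.4 and 475 CPM. Among the genes that ran in opposite directions were glutathione transferase genes. Gsta1 stood at 146 and 15.3 CPM in colon and at 71.8 and 1421.5 CPM in the small intestine. Gsta4 stood at 85.3 and 3.07 CPM and at 18.0 and 245 CPM in the same order. Gstm1 stood at 80.2 and 10.5 CPM and at 34.1 and 548 CPM. The phosphate carrier Slc34a2 stood at 12.9 and 57.8 CPM in colon and 348 and 2.68 CPM in the small intestine. Of 28 genes at least 4-fold apart between the ends of both organs in absorptive cells 12 ran in the same and 16 in the opposite direction by label. Under exchanged colon labels, which stay open as described above, these counts would change places.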
